A study of Rattus norvegicus with 6 samples.

How the data were processed

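The series holds 6 Illumina rat expression BeadChip arrays, 3 from day 1 and 3 from day 3 after implantation. Per the labels every array comes from a different rat, so no sample is paired and the comparison was unpaired. The labels give 100 ng of total RNA per labelling, with biotin-labelled RNA made by the Illumina TotalPrep kit. The values used are the authors' deposited quantile-normalised intensities on the linear scale, with a median of 104, a lowest value of 60.6 and a highest of 45354 on each array. Sorted, the 6 arrays held the same values within 0.01 at all but 61 of 22517 ranks, and differed there by at most 22.3. They are not log-transformed. The submitters' processing notes name limma. The scanner's background setting and the arrays normalised together are not given in the sources used here. Of 2395 values between 1100 and 9000, 83.2% were whole within 0.02 after multiplication by 12 with the decimal point moved by 3 places, against 40.7% with 6 in place of 12.

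The design fixed before the data were examined called for the non-normalised table with its detection p-values (limma's neqc). That table holds 12 columns, 6 of signal and 6 of detection, whose names match no sample label, so it was not used here. The deposited intensities were used in its place, with the fallback that the design named: normexp background correction with offset 50, quantile normalisation and log2. In place of the detection p-values, background was estimated from the values themselves. The mode of the intensities was 86.0, and the limit was 101, the 95th percentile of a normal distribution on the log2 scale with that mode and the SD of the values below it. Probes above the limit on at least 3 of the 6 arrays were kept, which left 12170 of 22517. A fold against a day with 0 arrays above the limit is given as a bound, computed with that day at the limit.

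Of the 22517 probes 13787 carried 1 gene symbol, 0 carried several and 8730 had no symbol in the annotation used here. They covered 13336 genes, of which 8674 had a kept probe. Each gene is represented by its kept probe with the highest mean value. Of 158 kept genes with more than 1 probe, 0 had probes that passed in opposite directions. List members were matched by current symbol, then by earlier symbols where no current gene carries that name.

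Each probe was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with 1 coefficient for day and a two-sided moderated test. P-values were adjusted by Benjamini and Hochberg over all kept probes, with 0.05 as the threshold. The 43 gene lists of cell types and functions, fixed with the design, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Beside it stand camera with an estimated correlation, fry, and each list's members adjusted over the list alone. The lists are those for which the report gives a count and a median.

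Genes were named by a rule. It took the 10 with the largest positive and the 10 with the largest negative difference among genes past the threshold whose days did not overlap. It also took up to 2 members per list and direction that changed most, or the 2 brightest where none passed, and Actb, Gapdh, Hprt1, Ppia, Col1a1, Col3a1, Il1b, Il6, Tnf, Vegfa, Acta2, Pecam1 and Cd68 where kept. Genes outside the rule are said to be chosen after their values were seen.

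The pipeline was tested on simulated data of 12170 probes on 6 arrays with 200 changed. It called 4.48% of 67 probes changed by 0.5 on the log2 scale, 68.7% of 67 changed by 1 and 97.0% of 66 changed by 2. It made 7 false calls among 120, and 0 calls where nothing was changed. The simulated values were independent between probes and equally variable on all arrays, unlike the data. These rates therefore test the pipeline and do not carry over to the counts below. The number of arrays limits the precision of every value.

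Alternatives were no background correction, which gives the deposited values on the log2 scale, cyclic loess, no filter and a filter at the 99th percentile on all 6 arrays. Others were a trend and robust variance model, array weights, a plain test per probe without moderation, leaving out each array in turn, other set tests and other choices of probe per gene. Normexp with offset 16, values below background raised to the limit, the complement list without F13a1, and the list counts and medians with each array left out, with their limits of 1.5 times and 0.1, were chosen after seeing the data.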

Results

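RNA was measured in the tissue that grew into uncoated cellulose implants under the skin of 6 Sprague-Dawley rats aged 10 weeks, with 1 Illumina rat BeadChip array per rat. Rats 1, 2 and 3 gave tissue at day 1 (24 hours after implantation), and rats 4, 6 and 7 gave tissue at day 3 (72 hours). Every array held 22517 probe intensities with a median of 104, of which 11927 (53.0%) lay above the estimated background. The test covered 12170 probes, among them probes for 8674 named genes. Across these probes the day 3 arrays correlated with each other at r = 0.988 to 0.992, and rat 1 with rat 2 at r = 0.991. Rat 3 correlated with rats 1 and 2 at r = 0.957 and 0.964. Between the days r ran from 0.922 (rats 3 and 7) to 0.964 (rats 1 and 4), reaching rat 3's values with its own day. These correlations are across probes, which are not independent replicates. Adipocyte genes were higher in rat 3 than in rats 1 and 2 by a median of 3.35 on the log2 scale. Where leaving out 1 array changed the number of rising or falling members of a list by more than 1.5 times, or turned its median or moved it by as much and over 0.1, the numbers risen and fallen in that refit are given beside the list as "5 and 3 without rat 1".

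The comparison of day 3 with day 1 follows gene expression in the implant over the early days of tissue growth. Intervals of list medians run over the genes of a list, not over rats, and these genes are not independent. Of 14 measured collagens 12 rose from day 1 to day 3, with a list median of 2.32 on the log2 scale (95% interval 0.77 to 3.24), as did 30 of 36 cell cycle genes (median 1.51) and 12 of 17 fibroblast markers (median 1.57). Of 14 neutrophil markers 10 fell (median -1.65), as did 8 of 9 mast cell markers (median -1.35) and 10 of 13 pro-inflammatory cytokines and mediators (median -1.31). Each of these 6 lists passed the camera test with its preset correlation and did not pass when the correlation was estimated (adjusted p = 0.269 with an estimated correlation for each). Col1a1, a chain of type I collagen, went from 10.41 ± 0.48 to 14.61 ± 0.13 (log2 intensity, mean ± SD, n = 3 rats per day), an 18.4-fold rise. Hdc, the enzyme that makes histamine, went from 11.73 ± 1.06 to 8.0 ± 0.34, a 13.3-fold fall.

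In the limma test 2729 probes passed an adjusted p of 0.05, of which 1523 were higher at day 3 and 1206 higher at day 1. Of these probes, 954 also differed at least 2-fold, 526 upward and 428 downward. The number of probes past the test was 1316 without rat 2, 1343 without rat 6, 1460 without rat 7 and 3800 without rat 3. By gene, 1175 rose and 931 fell. The 3 values of each day lay apart for 4829 probes (39.7%), where chance gives 10%. Over the 43 lists, members counted in each list they belong to, 193 rose and 125 fell; there were 173 and 85 without rat 1, 135 and 72 without rat 2, 225 and 193 without rat 3, 172 and 109 without rat 4, 139 and 90 without rat 6, and 151 and 80 without rat 7. Of the 43 gene lists, 20 passed the camera test with its preset correlation, 10 toward day 3 and 10 toward day 1, and 0 passed with an estimated correlation. The complement list's estimated correlation, 0.0045, was under the preset 0.01, yet its camera adjusted p went from 0.0935 to 0.292. Falling short with an estimated correlation therefore does not show that a list was unchanged.

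Differences below are day 3 minus day 1 on the log2 scale with the SE of the fit, each from 3 rats per day. The 116 named genes that passed the test had adjusted p from 0.000135 to 0.0458, and in each of them the 3 arrays of 1 day lay above the 3 arrays of the other. Of these genes 62 also passed a test per probe without moderation, and 54 did not. In each of 6 refits that left out 1 array 74 passed. For the other 42, the highest adjusted p among the refits is printed with the rat left out, as in "0.0732 without rat 2". For 6 of the 116 only 1 or 2 of the 3 arrays of a day lay above background. Beside their differences stands the difference with values below background at the limit, a setting chosen after seeing the data.

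The gene that rose most was Cthrc1, a secreted protein with a collagen-like repeat, by 4.90 (SE 0.17, 29.8-fold, adjusted p = 0.000135). It was followed by Col1a1 (4.2, SE 0.24) and by Lrrc15, a membrane protein with leucine-rich repeats (4.2, SE 0.16). Next came Col5a1, a chain of type V collagen (3.93, SE 0.27), and Olfml3, an olfactomedin-like secreted protein (3.70, SE 0.14). Lrrc17 rose by 3.54 (SE 0.13) and Fbn2, a fibrillin of microfibrils, by 3.42 (SE 0.16). The day 1 levels of Lrrc15 and Fbn2, 6.66 and 6.67, lay near the background limit of 6.42 on this scale. The size of their rises therefore depends on the background correction and its offset. Aspn, a small leucine-rich proteoglycan, rose by 3.30 (SE 0.24). Msln, a surface protein of mesothelial cells, rose by 3.29 (SE 0.48), and Col3a1, the chain of type III collagen, by 3.24 (SE 0.14, 9.46-fold).

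Among the genes that fell most, Hdc fell by 3.73 (SE 0.50, adjusted p = 0.00447). Its day 1 levels were 12.50 in rat 1, 12.16 in rat 2 and 10.52 in rat 3. Retnlg, a resistin-like protein of granulocytes, fell by 3.72 (SE 0.78, adjusted p = 0.0189, 0.0732 without rat 2). Scd, the desaturase that makes monounsaturated fatty acids, fell by 3.67 (SE 0.68, adjusted p = 0.0126, 0.0526 without rat 7); its level was 15.25 in rat 3 against 12.49 in rat 1 and 12.98 in rat 2. Gnmt, a glycine methyltransferase, fell by 3.05 (SE 0.38), and the carboxylesterase Ces1c by 2.78 (SE 0.65, 0.0916 without rat 2). Acod1, which makes itaconate in activated macrophages, fell by 2.77 (SE 0.29), and the thioesterase Olah by 2.73 (SE 0.18). Gldn, above background on 1 of 3 day 3 arrays, fell by 2.69 (SE 0.51, 0.058 without rat 2; 2.60 at the limit). Ass1, an enzyme of arginine synthesis, fell by 2.64 (SE 0.26). Pglyrp1, a peptidoglycan-binding protein of neutrophil granules, fell by 2.57 (SE 0.35).

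**Figure D1:**
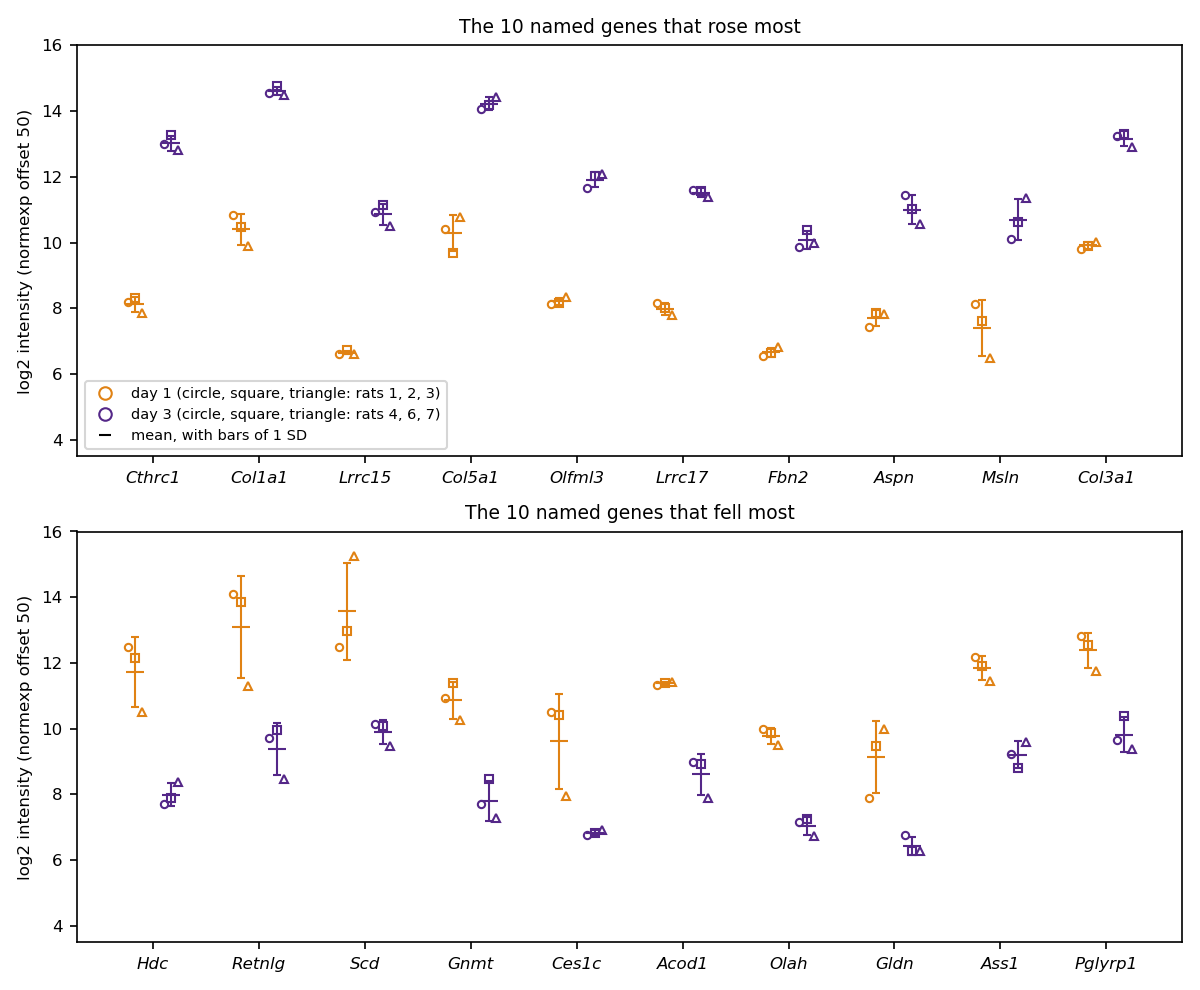
Log2 intensity (normexp offset 50) of the 10 named genes that rose most and the 10 that fell most, with 3 arrays per day as symbols and the mean with bars of 1 SD. Cthrc1 lies near 8.13 at day 1 and 13.03 at day 3. The values of the 2 days do not overlap in any of the 20 genes, as the rule for naming them required.

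Collagens had 12 members that rose, 0 that fell and 2 that did not pass (13 and 0 adjusted over the list alone; camera adjusted p = 6.08e-10, and adjusted p = 0.269 with an estimated correlation). The members short of the test, named after their values were seen, were Col1a2 with 0.33 (SE 0.12) and Col7a1 with 0.11 (SE 0.23). Col1a2 had levels of 14.76 at day 1 and 15.08 at day 3, near the highest value of any probe, 15.47. Among enzymes that process and cross-link collagen 18 rose, 1 fell and 4 did not pass (18 and 1 adjusted over the list alone; 17 and 0 without rat 1, 4 or 7, 13 and 0 without rat 2, 18 and 2 without rat 3 and 15 and 0 without rat 6). Their median was 1.09, with camera adjusted p = 2.48e-09 and adjusted p = 0.269 with an estimated correlation. Pcolce, the enhancer of procollagen C-proteinase, rose by 3.20 (SE 0.12) and the lysyl oxidase Loxl1 by 2.43 (SE 0.16). The transglutaminase Tgm2 fell by 0.82 (SE 0.20, 0.0995 without rat 2). Of 29 matrix glycoproteins and proteoglycans 19 rose, 1 fell and 9 did not pass (21 and 2 adjusted over the list alone; 19 and 0 without rat 1, 19 and 2 without rat 3, 18 and 0 without rat 4 or 7 and 16 and 0 without rat 6), with a median of 1.33. Their camera adjusted p was 3.87e-09, and adjusted p = 0.269 with an estimated correlation. Fbn2 and Aspn led this list, and Vcan, the proteoglycan versican, fell by 0.88 (SE 0.18, 0.0627 without rat 6).

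Fibroblast markers counted 12 that rose, 0 that fell and 5 that did not pass (14 and 1 adjusted over the list alone; 12 and 2 without rat 3). Their camera adjusted p was 5.32e-08, and adjusted p = 0.269 with an estimated correlation. Pcolce and Mfap5, a microfibril glycoprotein (3.09, SE 0.32), rose most. Of the 17 fibroblast markers 8 are also in other lists, Pcolce among them, so the rises of these lists are not separate. The median of 12 smooth muscle, pericyte and myofibroblast markers was 0.69, with 5 that rose, 0 that fell and 7 that did not pass (6 and 0 adjusted over the list alone; 2 and 0 without rat 2 or 6, 8 and 0 without rat 3 and 3 and 0 without rat 7). Here camera gave adjusted p = 0.00196, and adjusted p = 0.329 with an estimated correlation. Myl9, a myosin light chain of smooth muscle, rose by 1.65 (SE 0.17) and the actin-binding caldesmon Cald1 by 1.11 (SE 0.22). In the list of 16 endothelial markers 9 rose, 0 fell and 7 did not pass (9 and 0 adjusted over the list alone; 5 and 0 without rat 2 or 6), with a median of 0.76. Its camera adjusted p was 0.000167, and adjusted p = 0.269 with an estimated correlation. The apelin receptor Aplnr rose by 1.95 (SE 0.21) and Vwf, the von Willebrand factor, by 1.61 (SE 0.33, 0.0685 without rat 6).

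Of 36 cell cycle genes 30 rose, 0 fell and 6 did not pass (32 and 0 adjusted over the list alone). The camera adjusted p was 1.14e-16, and adjusted p = 0.269 with an estimated correlation. Ccnb2, a cyclin of mitotic entry, rose by 2.88 (SE 0.26) and the mitotic kinase Plk1 by 2.80 (SE 0.32). Among 43 ribosomal proteins the median was 0.28, with 8 that rose, 0 that fell and 35 that did not pass (8 and 0 adjusted over the list alone; 4 and 0 without rat 1, 1 and 0 without rat 2, 6 or 7 and 2 and 0 without rat 4). Camera gave adjusted p = 8.26e-05, and adjusted p = 0.269 with an estimated correlation. Rpl30 rose by 0.98 (SE 0.12) and Rps15 by 0.56 (SE 0.15, 0.123 without rat 7). The WNT pathway list, with a median of 0.06 over 17 genes (0.00063 with values below background at the limit), had 7 that rose, 0 that fell and 10 that did not pass (7 and 0 adjusted over the list alone; 3 and 0 without rat 2, 4 and 0 without rat 6 and 4 and 0 (median -0.01) without rat 7). It had camera adjusted p = 0.0322 (0.0573 without rat 3, 0.0521 without rat 7), and adjusted p = 0.324 with an estimated correlation. The secreted WNT binders Sfrp4 and Sfrp2 rose by 2.44 (SE 0.14) and 2.32 (SE 0.47, 0.0649 without rat 7). All 3 measured epidermal keratinocyte markers rose (3 and 0 adjusted over the list alone), with a median of 0.53 (0.33 with the 2 bounds below in place), camera adjusted p = 0.0196 (0.322 with no filter on dim probes) and adjusted p = 0.269 with an estimated correlation. They were Pkp1, a desmosomal plakophilin above background on 1 of 3 day 1 arrays, with 0.89 (SE 0.17, 0.0504 without rat 2; 0.75 at the limit), the keratin Krt10 and, named after its values were seen, the transcription factor Tp63. Krt10 and Tp63 were above background on 0 day 1 arrays, so their folds are bounds, taken against the background limit of 101. Krt10 was at least 1.25-fold higher at day 3 (0.062 without rat 6, and adjusted p = 0.0575 with values below background at the limit) and Tp63 at least 1.21-fold.

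Neutrophil markers counted 0 that rose, 10 that fell and 4 that did not pass (1 and 11 adjusted over the list alone; 1 and 9 without rat 1). The camera adjusted p was 6.68e-06, and adjusted p = 0.269 with an estimated correlation. Mmp8, the neutrophil collagenase, fell by 2.56 (SE 0.28) and Hp, haptoglobin, by 2.50 (SE 0.26). Of 21 neutrophil markers with a probe here 14 were kept. Among those too dim to be kept were S100a9, Fpr1, Ltf and Ngp. Of the mast cell markers 0 rose, 8 fell and 1 did not pass (0 and 8 adjusted over the list alone; 0 and 4 without rat 2 and 0 and 5 without rat 7), with camera adjusted p = 8.64e-05 and adjusted p = 0.269 with an estimated correlation. Besides Hdc, the tryptase Tpsab1 fell by 2.28 (SE 0.24). Pro-inflammatory cytokines and mediators had 0 that rose, 10 that fell and 3 that did not pass (0 and 12 adjusted over the list alone), with camera adjusted p = 2.69e-07 and adjusted p = 0.269 with an estimated correlation. Il1a fell by 2.51 (SE 0.41) and Nos2, the inducible nitric oxide synthase, by 2.44 (SE 0.46). Il1b fell by 1.99 (SE 0.45, 0.0792 without rat 2). Its day 1 levels of 14.93, 14.96 and 15.11 lay near the highest value of any probe, 15.47. Il6 fell by 1.25 (SE 0.18) and Tnf, above background on 2 of 3 day 3 arrays, by 0.86 (SE 0.14; 0.81 at the limit).

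In 17 CC and CX3C chemokines, with a median of -0.77, 1 rose, 5 fell and 11 did not pass (1 and 8 adjusted over the list alone; 1 and 3 without rat 1, 0 and 3 without rat 2, 2 and 10 without rat 3, 0 and 5 without rat 6 and 0 and 4 without rat 7). Their camera adjusted p was 0.0175, and adjusted p = 0.269 with an estimated correlation. The monocyte attractant Ccl7 fell by 2.14 (SE 0.28) and Ccl4 by 2.33 (SE 0.60, 0.117 without rat 7). Cx3cl1 rose by 0.67 (SE 0.15, 0.0853 without rat 6). The 12 CXC chemokines had a median of -1.08, with 3 that rose, 6 that fell and 3 that did not pass (3 and 7 adjusted over the list alone; 3 and 3 without rat 1, 2 and 2 without rat 2, 1 and 3 without rat 6 and 3 and 2 without rat 7; camera adjusted p = 0.101, 0.0434 without rat 6). Cxcl13, which attracts B cells, rose by 2.31 (SE 0.47, 0.0664 without rat 6) and Cxcl9 by 1.56 (SE 0.30, 0.0565 without rat 6). The neutrophil attractant Cxcl1 fell by 2.46 (SE 0.55, 0.0837 without rat 2) and Cxcl11 by 2.01 (SE 0.43, 0.0745 without rat 2). Interferon response genes had a median of -0.58 over 20, with 1 that rose, 3 that fell and 16 that did not pass (1 and 3 adjusted over the list alone; 2 and 1 without rat 1, 0 and 1 without rat 2 or 7 and 1 and 10 without rat 3). They had camera adjusted p = 0.0143 (0.145 without rat 1), and adjusted p = 0.684 with an estimated correlation. Ifit1 fell by 2.24 (SE 0.38) and Cxcl10 by 1.31 (SE 0.31, 0.095 without rat 2). Ifi27 rose by 0.81 (SE 0.16, 0.058 without rat 2).

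Anti-inflammatory and alternative activation genes had a median of -0.64 over 19, with 2 that rose, 6 that fell and 11 that did not pass (2 and 10 adjusted over the list alone; 2 and 3 without rat 1, 2 or 4 and 2 and 10 without rat 3). Camera gave adjusted p = 0.0219, and adjusted p = 0.461 with an estimated correlation. Chi3l1, a chitinase-like protein, fell by 2.29 (SE 0.14) and Il1rn, the antagonist of the interleukin-1 receptor, by 2.33 (SE 0.59, 0.111 without rat 2). Il1rl1, the receptor of interleukin-33, rose by 1.81 (SE 0.23) and the haemoglobin scavenger receptor Cd163 by 0.88 (SE 0.12). Of 23 immediate early genes 0 rose, 11 fell and 12 did not pass (0 and 15 adjusted over the list alone; 0 and 6 without rat 1 or 2, 0 and 17 without rat 3 and 0 and 7 without rat 6), with a median of -0.72. Their camera adjusted p was 1.01e-06, and adjusted p = 0.269 with an estimated correlation. Ier3 fell by 1.52 (SE 0.26) and Junb by 1.46 (SE 0.33, 0.0789 without rat 2). Of 25 hypoxia and glycolysis genes 0 rose, 17 fell and 8 did not pass (0 and 22 adjusted over the list alone), with a median of -0.85. Their camera adjusted p was 2.80e-10, and adjusted p = 0.269 with an estimated correlation. Ero1a, an oxidase of the endoplasmic reticulum, fell by 2.00 (SE 0.32) and Pdk1, which inhibits pyruvate dehydrogenase, by 1.36 (SE 0.17). Oxidative stress and metallothionein genes had a median of -0.53 over 24, with 3 that rose, 9 that fell and 12 that did not pass (3 and 12 adjusted over the list alone; 5 and 12 without rat 3). Camera gave adjusted p = 0.00399, and adjusted p = 0.269 with an estimated correlation. Mitochondrial superoxide dismutase Sod2 fell by 1.63 (SE 0.17) and Ncf4, a subunit of the phagocyte NADPH oxidase, by 1.49 (SE 0.17). The metallothionein Mt3 rose by 2.49 (SE 0.37) and Gstp1 by 0.92 (SE 0.09), with 0.30 (adjusted p = 0.19) at the other probe of Gstp1.

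The 16 adipocyte markers had a median of -1.38, with 0 that rose, 2 that fell and 14 that did not pass (0 and 2 adjusted over the list alone; 0 and 2 (median -2.16) without rat 1, 3 and 3 (median -0.01) without rat 3 and 0 and 1 without rat 7). Camera gave adjusted p = 0.0219 (0.759 without rat 3), and adjusted p = 0.684 with an estimated correlation. All 16 were higher in rat 3 than in the mean of rats 1 and 2, by a median of 3.35. Scd and the triglyceride-making enzyme Dgat2 fell; Dgat2 did so by 2.53 (SE 0.38), with levels of 13.28, 13.25 and 13.82 in rats 1, 2 and 3. The 16 skeletal muscle markers had a median of -1.0, with 0 that rose, 1 that fell and 15 that did not pass (0 and 1 adjusted over the list alone; 0 and 3 (median -1.64) without rat 1, 0 and 1 (median -0.59) without rat 2, 0 and 1 (median -0.63) without rat 3 or 4, 0 and 1 (median -1.53) without rat 6 and 0 and 1 (median -0.65) without rat 7; camera adjusted p = 0.0533, 0.000164 without rat 1, 0.000701 without rat 6, 0.0372 with no filter on dim probes and 0.0496 with offset 16, chosen after seeing the data). In rat 3, 14 of the 16 were higher, by a median of 0.98. Tnnc1, the slow-muscle and cardiac troponin C, fell by 1.09 (SE 0.16). Of 26 oxidative phosphorylation genes 0 rose and 0 fell, also adjusted over the list alone, and 26 did not pass (median -0.20, camera adjusted p = 0.149, 0.0106 without rat 1 and 0.00619 without rat 2). In rat 3, 25 of the 26 were higher, by a median of 1.19. The list's median was -0.35 without rat 1, -0.37 without rat 2, each with 0 that rose and 0 that fell, and 0.16 without rat 3, with 4 that rose and 1 that fell. Cox6a1 differed by 0.06 (SE 0.20) and Atp5f1b by 0.09 (SE 0.35). The day 1 level of Cox6a1, 14.83, lay near the highest value of any probe, 15.47. Both genes were below 0 under cyclic loess, at -0.042 and -0.011.

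**Figure D2:**
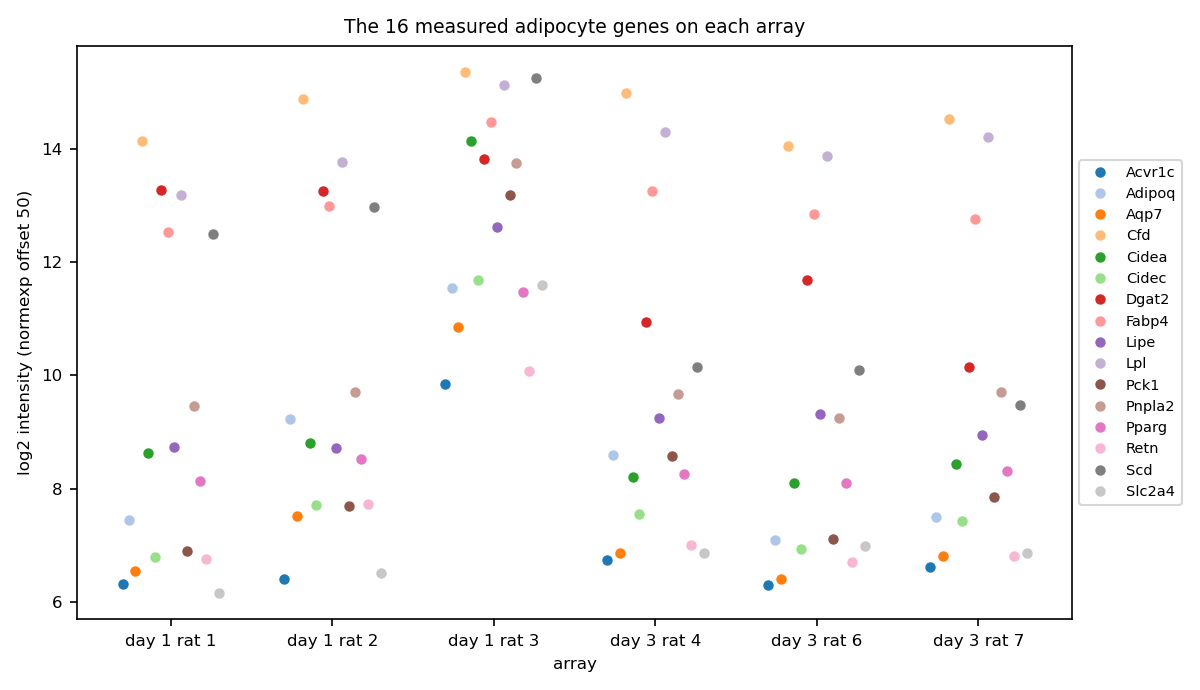
Log2 intensity (normexp offset 50) of the 16 measured adipocyte genes, each a colour and set apart sideways, on the 6 arrays. All 16 lie higher in rat 3 than in each of rats 1 and 2. Adipoq, named after its values were seen, lies at 11.54 in rat 3 and at 7.44 and 9.23 in rats 1 and 2.

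The macrophage list did not pass (camera adjusted p = 0.0978; 0.0363 without rat 1, 0.0237 without rat 6 and 0.0422 without rat 7), with a median of 0.36 over 16 genes. In it 6 rose, 1 fell and 9 did not pass (6 and 2 adjusted over the list alone; 6 and 2 (median -0.0031) without rat 4 and 6 and 1 (median 0.57) without rat 6). Apoe, the lipid carrier apolipoprotein E, rose by 2.09 (SE 0.18) and the complement subunit C1qa by 1.69 (SE 0.29). Cd14, a receptor for bacterial lipopolysaccharide, fell by 1.97 (SE 0.25). The list of complement components, as fixed, also held F13a1, a subunit of coagulation factor XIII. It had a median of 0.34 over 17, with 8 that rose, 1 that fell and 8 that did not pass (8 and 1 adjusted over the list alone; 7 and 0 (median 0.15) without rat 1, 6 and 0 (median -0.06) without rat 2, 10 and 3 (median 0.82) without rat 3, 7 and 0 without rat 6 and 6 and 1 (median 0.51) without rat 7; camera adjusted p = 0.0935, 0.0372 without rat 6 and 0.0372 with no filter). The member that fell was F13a1, by 1.36 (SE 0.32, 0.0953 without rat 2), and C1qc rose by 1.62 (SE 0.24). Without F13a1, left out after its values were seen, 8 of 16 rose, 0 fell and 8 did not pass, with a median of 0.43 (0.21 without rat 2 and 0.88 without rat 3, where 10 rose and 2 fell). Camera then gave adjusted p = 0.0343 (0.0557 without rat 4), and adjusted p = 0.252 with an estimated correlation. Antigen presentation and dendritic cell markers had a median of 0.00 over 14, with 4 that rose, 2 that fell and 8 that did not pass (5 and 3 adjusted over the list alone; 2 and 0 (median 0.11) without rat 1, 2 and 0 without rat 2, 3 and 5 (median -0.10) without rat 3, 1 and 1 (median -0.03) without rat 4 and 1 and 0 without rat 6 or 7; camera adjusted p = 0.803). RT1-Db1, a class II chain, rose by 1.07 (SE 0.16) and RT1-Ba by 1.12 (SE 0.25, 0.0721 without rat 7). RT1-DMa, of the class II peptide loader, fell by 0.99 (SE 0.23, 0.0945 without rat 6) and Irf8, above background on 2 of 3 day 3 arrays, by 0.59 (SE 0.15, 0.113 without rat 2; 0.53 at the limit). The 17 T and NK cell markers had a median of -0.08 (95% interval -0.37 to 0.17), with 1 that rose, 0 that fell and 16 that did not pass (0 and 0 adjusted over the list alone; 0 and 0 without rat 2, 4, 6 or 7 and 0 and 6 (median -0.22) without rat 3; camera adjusted p = 0.691, 0.0479 without rat 3). In rat 3 only 1 of these 17 markers was higher than in the mean of rats 1 and 2, with a median of -0.72. The granzyme Gzma, above background on 1 of 3 day 1 arrays, rose by 0.44 (SE 0.12, 0.13 without rat 2; 0.38 at the limit). None of the 3 B cell and plasma cell markers passed (0 and 0 adjusted over the list alone; 0 and 1 without rat 3; median -0.10, camera adjusted p = 0.388), Cd79b differing by -0.10 (SE 0.10) and Xbp1 by -0.37 (SE 0.12). Of 9 erythroid and blood markers 0 rose, 1 fell and 8 did not pass (0 and 0 adjusted over the list alone; 0 and 0 (median -0.04) without rat 2 and 0 and 0 without rat 4 or 7; median -0.14, camera adjusted p = 0.208), and the globin Hbb-b1 fell by 1.11 (SE 0.28, 0.116 without rat 7). Of 3 platelet markers 0 rose, 1 fell and 2 did not pass (1 and 1 adjusted over the list alone; 0 and 1 (median -0.27) without rat 1 or 2, 0 and 2 (median -0.77) without rat 3 and 0 and 0 without rat 6 or 7; median -0.44, camera adjusted p = 0.58). The chemokine Ppbp was above background on 0 day 3 arrays and at least 3.20-fold higher at day 1 (0.0566 without rat 7).

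Coagulation and fibrinolysis genes had 6 that rose, 6 that fell and 6 that did not pass (7 and 6 adjusted over the list alone; 5 and 3 without rat 1, 5 and 1 without rat 2, 3 and 3 without rat 6 and 4 and 3 without rat 7; median -0.15, camera adjusted p = 0.934 in the other direction from the median). Besides Vwf, the thrombin receptor F2r rose by 1.38 (SE 0.14). Besides F13a1, coagulation factor F5 fell by 1.31 (SE 0.24, 0.0514 without rat 2). Matrix proteases and inhibitors had 2 that rose, 3 that fell and 16 that did not pass (2 and 3 adjusted over the list alone; 3 and 1 without rat 1, 1 and 1 without rat 2, 6 or 7, 5 and 4 without rat 3 and 2 and 2 (median 0.16) without rat 4; median 0.26, camera adjusted p = 0.698). Mmp23 rose by 2.22 (SE 0.15) and Mmp19 by 0.68 (SE 0.15, 0.0834 without rat 2). Besides Mmp8, the gelatinase Mmp9 fell by 1.32 (SE 0.33, 0.102 without rat 6). Of 8 hyaluronan genes 1 rose, 0 fell and 7 did not pass (1 and 0 adjusted over the list alone; 1 and 1 (median 0.19) without rat 3, 2 and 0 without rat 4 and 1 and 0 (median 0.28) without rat 7; median 0.45, camera adjusted p = 0.227). It was Hmmr, a hyaluronan receptor also found at the mitotic spindle, with 1.28 (SE 0.20). Angiogenic factors and receptors had 4 that rose, 1 that fell and 16 that did not pass (4 and 1 adjusted over the list alone; 5 and 0 without rat 1, 4 and 0 without rat 2 and 7 and 3 without rat 3; median 0.23, camera adjusted p = 0.179). Besides Aplnr, the lymphatic growth factor Vegfc rose by 1.43 (SE 0.12), and Vegfa fell by 1.10 (SE 0.23, 0.0548 without rat 1). Growth factors and receptors of repair had 3 that rose, 1 that fell and 12 that did not pass (3 and 1 adjusted over the list alone; 2 and 0 without rat 2, 4 or 7; median 0.06, camera adjusted p = 0.499). Igfbp6 rose by 2.02 (SE 0.36) and the receptor Pdgfra by 1.42 (SE 0.14), and Ereg, epiregulin, fell by 0.49 (SE 0.10, 0.0682 without rat 2).

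TGF-beta and BMP pathway genes had 6 that rose, 4 that fell and 18 that did not pass (7 and 5 adjusted over the list alone; 4 and 2 without rat 1 or 7, 3 and 1 without rat 2 and 3 and 2 without rat 6; median 0.07, camera adjusted p = 0.691). Fstl1 rose by 1.78 (SE 0.20) to a level of 14.79, near the highest value of any probe, 15.47. Ltbp2, a latent TGF-beta binding protein, rose by 1.07 (SE 0.21, 0.0618 without rat 6). The inhibitory Smad7 fell by 0.89 (SE 0.08) and Id2 by 1.27 (SE 0.29, 0.0868 without rat 2). Of 12 integrins 4 rose, 2 fell and 6 did not pass (5 and 2 adjusted over the list alone; 2 and 3 without rat 1, 2 and 1 without rat 2, 6 and 3 (median 0.42) without rat 3, 4 and 2 (median 0.24) without rat 4 and 2 and 2 without rat 6 or 7; median 0.14, camera adjusted p = 0.471). The collagen-binding Itga11, above background on 2 of 3 day 1 arrays, rose by 2.37 (SE 0.22; 2.35 at the limit) and Itgb5 by 2.31 (SE 0.26). Itgam, the myeloid CD11b chain, fell by 1.66 (SE 0.20) and Itgb7 by 1.52 (SE 0.28, 0.0536 without rat 2). Stem cell and homing genes had 5 that rose, 3 that fell and 9 that did not pass (5 and 3 adjusted over the list alone; 4 and 2 (median 0.09) without rat 2 and 5 and 5 (median 0.11) without rat 3; median 0.22, camera adjusted p = 0.55). Thy1 rose by 2.06 (SE 0.27) and Nes, the intermediate filament nestin, by 1.98 (SE 0.20). Cxcr4 fell by 1.45 (SE 0.33, 0.0834 without rat 2) and Csf3 by 1.31 (SE 0.26, 0.0629 without rat 7). Of 9 Schwann cell and nerve markers 3 rose, 0 fell and 6 did not pass (3 and 0 adjusted over the list alone; 2 and 0 (median 0.02) without rat 2 and 3 and 1 (median 0.23) without rat 3; median -0.04, camera adjusted p = 0.503 in the other direction). Gap43, a growth cone protein, rose by 2.57 (SE 0.30), and Ncam1, above background on 0 day 1 arrays, was at least 1.92-fold higher at day 3. Bone and cartilage genes had 0 that rose, 1 that fell and 7 that did not pass (1 and 1 adjusted over the list alone; 0 and 1 (median 0.07) without rat 1, 1 and 1 without rat 3 and 0 and 1 (median 0.04) without rat 7; median -0.01, mean 0.08, camera adjusted p = 0.934 toward day 1). Alpl, an alkaline phosphatase, fell by 0.73 (SE 0.10).

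Heat shock and unfolded protein response genes had 1 that rose, 4 that fell and 17 that did not pass (4 and 7 adjusted over the list alone; 0 and 2 (median -0.16) without rat 2, 2 and 7 without rat 3, 2 and 4 without rat 4, 0 and 3 without rat 6 and 1 and 2 without rat 7; median -0.28, camera adjusted p = 0.191). The small heat shock protein Hspb8 rose by 1.51 (SE 0.30, 0.0599 without rat 7), and Trib3 fell by 0.93 (SE 0.13) and Dnajb9 by 1.01 (SE 0.23, 0.0794 without rat 2). Lysosome and lipid handling genes had 4 that rose, 3 that fell and 19 that did not pass (5 and 4 adjusted over the list alone; 4 and 1 without rat 1, 2, 6 or 7 and 5 and 5 without rat 3; median -0.22, camera adjusted p = 0.388). Besides Apoe, the hexosaminidase Hexa rose by 1.19 (SE 0.11). The galactosidase Gla fell by 1.02 (SE 0.12) and Pla2g7 by 0.96 (SE 0.24, 0.121 without rat 6). Of 16 reference genes 2 rose, 1 fell and 13 did not pass (2 and 1 adjusted over the list alone; 3 and 2 without rat 3; median -0.06, camera adjusted p = 0.934 in the other direction). Actb differed by -0.05 (SE 0.10), Gapdh by -0.06 (SE 0.14), Hprt1 by -0.08 (SE 0.13) and Ppia by 0.30 (SE 0.10, adjusted p = 0.0741). Tubb5 rose by 1.06 (SE 0.15) and Gusb by 1.04 (SE 0.11), and Pgk1, an enzyme of glycolysis, fell by 0.63 (SE 0.10). Near the highest value of any probe, 15.47, lay Actb (15.10 at day 1), Ppia (14.98 at day 1) and Pgk1 (14.90 at day 1). Acta2, Pecam1 and Cd68 had no probe that carried their symbol here.

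**Figure D3:**
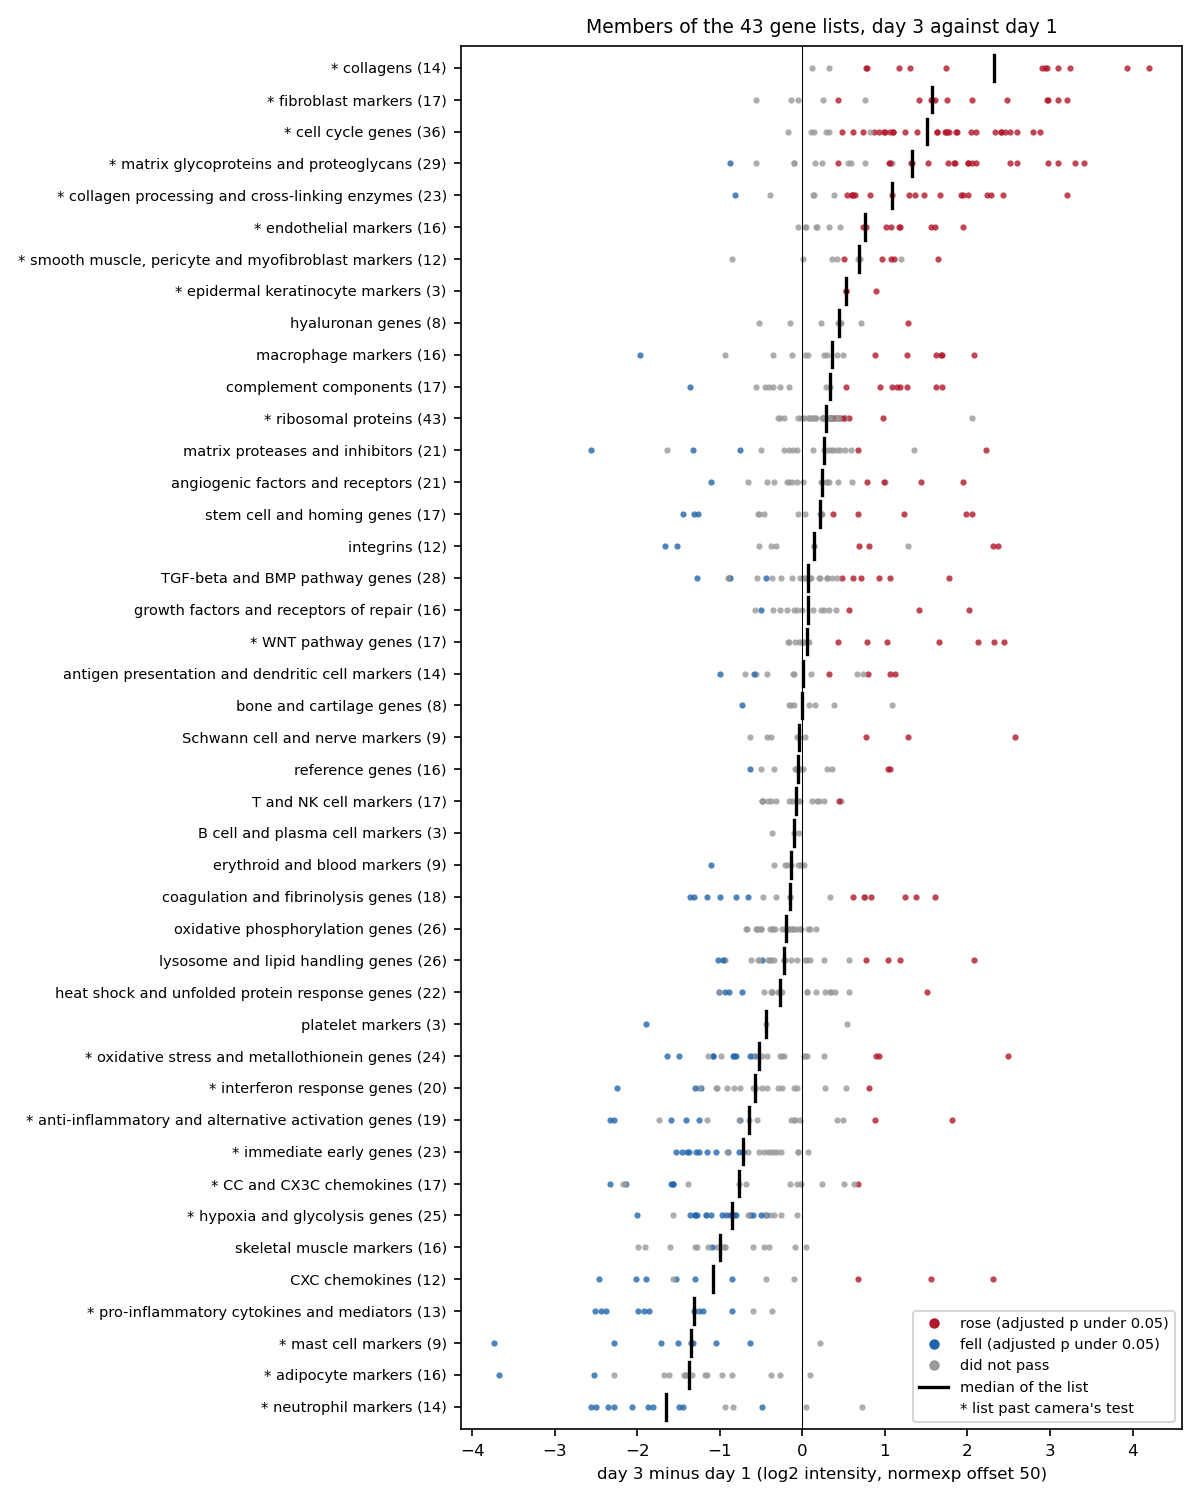
Day 3 minus day 1 (log2 intensity, normexp offset 50) for each measured member of the 43 gene lists, with list size in brackets, the list's median as a bar and a star where camera's test with its preset correlation passed. Red points rose, blue points fell and grey points did not pass an adjusted p of 0.05; the collagen median lies at 2.32 and the neutrophil median at -1.65.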

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

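Normexp with offset 16, values below background at the limit and the complement list without F13a1 were chosen after seeing the data; the other settings were planned. The 2729 probes past the test became 1057 under a test per probe without moderation (512 in place of 954 at 2-fold), and 1316 to 3800 when 1 array was left out, lowest without rat 2 and highest without rat 3. Of the 116 named genes past the test, 54 lost the call without moderation and 1, Krt10, with values below background at the limit (0.0575), where 2669 probes passed. Calls were also lost for 3 genes under the trend and robust model, 2 with no filter and 1 with array weights. Without F13a1 the complement list passed camera's test (0.0343), but not without rat 4 (0.0557) or with an estimated correlation (0.252). No probe called here changed sign under any setting that was run. For a probe whose days lie apart, as in the 116 named genes, hardly any setting but cyclic loess could have turned it. The other settings keep the differences, drop or weight arrays, or rescale them nearly alike. With an estimated correlation 0 lists passed: adjusted p was 0.269 for collagens, collagen processing, matrix glycoproteins, fibroblast, endothelial, keratinocyte, neutrophil, mast cell, cell cycle, ribosomal, pro-inflammatory, CC chemokine, immediate early, hypoxia and oxidative stress lists, 0.684 for adipocyte and interferon, 0.461 for anti-inflammatory, 0.329 for smooth muscle and 0.324 for WNT genes. Fry, which compares no list with other genes, had 23 lists past; it gave 0.381 for adipocyte and 0.226 for interferon genes, and passed complement (0.00547), angiogenic (0.0169), stem cell (0.0199), integrin (0.0322) and growth factor genes (0.0352). Array weights, with rat 3 at 0.267, gave 0.267 for adipocyte and 0.0632 for WNT genes, and turned antigen presentation (0.888), oxidative phosphorylation (0.999) and reference genes (0.999). Skeletal muscle genes passed with offset 16 (0.0496). Without the filter complement and skeletal muscle genes passed (both 0.0372), the keratinocyte list had 0.322 and the bone and cartilage list turned (0.947). Cyclic loess turned the reference genes (0.568), Cox6a1 (-0.042) and Atp5f1b (-0.011). Leaving out 1 array gave adjusted p of 0.000204 to 0.759 for adipocyte, 0.00111 to 0.145 for interferon and 0.0193 to 0.0573 for WNT genes. Directions turned in some of these refits for T and NK cell (0.0479 to 0.965), antigen presentation (0.558 to 0.911), bone (0.788 to 0.927), coagulation (0.857 to 0.995), matrix protease (0.447 to 0.997), oxidative phosphorylation (0.00619 to 0.218) and reference genes (0.850 to 0.995). They also turned for Actb (-0.10 to 0.017), Atp5f1b (-0.12 to 0.52), Cox6a1 (-0.11 to 0.27), Gapdh (-0.20 to 0.011) and Hprt1 (-0.17 to 0.0089), none past the test in the report. The cause of these changes was not tested. Not run were the settings that need detection p-values, median scaling after nec and the chip as a block. Signal over background limits what can be read, since 53.0% of probes lay above it.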

Other observations

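The gene families in this paragraph and the next, the genes named for rat 3 below, the test of the neutrophil share, the probes of 1 rat below the others and the setting at the background limit were chosen only after the results were seen. The splits of the arrays and the other tests on rat 3 were chosen before their own outcomes were seen. Rat 3 itself was picked for these tests because its array had been seen to stand apart. All 4 measured members of the prolyl 3-hydroxylase family rose, P3h4 by 2.78, P3h1 by 2.23, P3h3 by 1.83 and P3h2 by 0.55 on the log2 scale. Of 8 FK506-binding proteins, prolyl isomerases, 3 rose, 0 fell and 5 did not pass. Those that rose were Fkbp9 (2.48), Fkbp10 (2.28) and Fkbp7 (2.22). Of 3 calcium-binding reticulocalbins Rcn3 and Rcn1 rose by 2.92 and 1.79, and Rcn2 differed by 0.16 and did not pass. Both measured KDEL receptors, which return proteins to the endoplasmic reticulum, rose, Kdelr3 by 1.86 and Kdelr1 by 0.97. Of 8 genes of the COPII coat 4 rose, Sec16b most (2.12), 3 fell and 1 did not pass; those that fell were Sec24a, Sec24b and Sar1b by 0.47, 0.56 and 0.63. Of 17 kinesins 8 rose, 2 fell and 7 did not pass. The rise was led by Kif20a (2.51) and Kif22 (2.50), both of mitosis, and Kif1b and Kifc3 fell by 0.49 and 0.52.

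Of 15 C-type lectin genes 6 fell, 2 rose and 7 did not pass. Those that fell were led by Clec4e, a receptor for mycobacterial glycolipid, with -2.47 (SE 0.44), and by Clec4d with -2.07, while Clec2d rose by 1.13. Clec11a, above background on 1 of 3 day 1 arrays, rose by 1.29 (1.23 with values below background at the limit). Of 6 Toll-like receptors 4 fell, 0 rose and 2 did not pass, with Tlr6 at -1.40 and Tlr2 at -1.31; Tlr4 differed by -0.55 and did not pass. Of 13 arginine and nitric oxide genes 8 fell, 2 rose and 3 did not pass. The genes that fell had among them Ass1 (-2.64), Nos2 (-2.44), Gch1 (-1.89), the arginine transporter Slc7a2 (-1.60) and Arg1 (-1.41), and Ddah2 and Oat rose by 1.06 and 0.68. Members said to have risen or fallen passed the limma test with 3 rats per day, and none of them changed sign under cyclic loess. None did so without background correction or with offset 16. These last settings rescale 6 arrays of nearly the same sorted values alike, so they could hardly turn a gene whose days lie apart.

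Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many probes as the 2729 between the days, the real split itself, and the highest of the others gave 9. With 10 splits the share cannot fall under 10%.

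The array of rat 3 stood apart from those of rats 1 and 2: 148 probes lay over 4-fold above both, against 0 such probes for rat 1 and 0 for rat 2, led by Thrsp (6.70 above the mean of rats 1 and 2), Gpd1 (6.25) and Pck1 (5.89). Over 4-fold below both others lay 8 probes of rat 3, 15 of rat 1 and 0 of rat 2. The named genes farthest below in rat 3 were Rps9 (-4.40 from the mean of rats 1 and 2), Ccl20 (-3.15), Retnlg (-2.68), Ces1c (-2.49) and Lyl1 (-2.44). Of these Ccl20, Retnlg and Ces1c had levels of 7.51, 11.31 and 7.96, toward their day 3 means of 7.43, 9.38 and 6.84, while Rps9 and Lyl1 (6.73 and 9.38) lay away from theirs (11.72 and 11.25). Higher noise of that array stays open in part. It was tested over 8234 probes below background on all 6 arrays. There rat 3's differences from rats 1 and 2 had 1.07 and 1.05 times the SD of the difference between these rats. Those probes were picked for low values on every array, and quantile normalisation gave all arrays nearly the same values. The ratios therefore cannot decide about brighter probes. Noise independent between probes would raise and lower genes alike. All 16 adipocyte genes and 25 of 26 oxidative phosphorylation genes were higher in rat 3, which argues against such noise for these lists. For other probes it stays open. A candidate explanation is fat carried into the sample: the adipocyte list lay 3.35 higher, and 4 of its 16 genes are in other lists too. The skeletal muscle list lay 0.98 higher, just short of the level set for this test, and the keratinocyte list differed by -0.056. Of 26 oxidative phosphorylation genes 25 were higher in rat 3, by a median of 1.19. The abundant adipocyte genes Cfd, Lpl and Fabp4 had log2 levels of 15.36, 15.12 and 14.46 in rat 3, and 14 of the 16 were above background in all day 3 rats. Another point of the course from day 1 to day 3 stays open. Across probes, rat 3 minus rat 1 correlated with the day 3 mean minus rat 2 at r = 0.077. Rat 3 minus rat 2 correlated with the day 3 mean minus rat 1 at r = 0.27. The day 3 mean lay on rat 3's side of rats 1 and 2 for 94 of the 148 probes above and 5 of the 8 below, but these probes were picked for their values and decide nothing. Also open are a true difference between rats, which was not tested, and what lowered the genes below.

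The lists of neutrophil and of matrix genes moved in opposite directions. A lower share of neutrophil RNA alone would raise the markers of every other cell type alike. The low end of the fibroblast interval lay 0.26 above the high end for T and NK cells and 1.07 above that for mast cells. The fibroblast (0.43 to 2.48) and macrophage (-0.13 to 1.62) intervals overlapped. Since these intervals run over genes and not over rats, they decide nothing here. In the limma test 12 of 17 fibroblast markers rose and 8 of 9 mast cell markers fell (4 without rat 2). A rise of fibroblast markers goes with a lower neutrophil share. Only the fall of the mast cell markers argues against that share as the whole cause, and only for that list. Whether neutrophils express these mast cell genes too was not tested. A change in the number or the expression of fibroblasts, mast cells or neutrophils stays open, and whole tissue on arrays cannot separate these.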
